A study of Rattus norvegicus with 8 samples.

How the data were processed

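RNA sequencing was performed on hippocampal tissue of rats of 2 inbred strains, the spontaneously hypertensive rat (SHR) and the Wistar-Kyoto rat (WKY), at 32 weeks of age. There were 4 libraries per strain, and the strain and replicate number of each were taken from its sample title. The labels do not say whether the 8 libraries came from 8 separate animals, so the p-values measure the spread between these libraries, which may be technical.

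The authors deposited raw read counts per gene, as 1 matrix of the 8 libraries and as 8 single-library tables. The single-library tables held the same values as the matrix for all 8 libraries and all 32623 genes, so they were not analysed separately. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d were used with the rn6 genome build. The annotation release, the strand setting and any filter on reads are not given in the sources used here. The deposited counts were whole numbers, and in every library more genes had exactly 4 counts than exactly 3 (for example 431 against 319 genes in WKY replicate 1). Counts this low were therefore not treated as tallies of single fragments, and intervals from counting error were not used. Per the file headers, 4 single-library tables carried another number than the sample title. WKY replicates 3 and 4 were numbered 5 and 6 in the headers, and SHR replicates 3 and 4 were numbered 4 and 6. The titles were used throughout.

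Genes were identified in the files by Ensembl gene ID only. The reference gene table used here paired 0 of its entries with an Ensembl ID, so 0 of the 32623 IDs could be given a symbol, a position or a function. The 59 gene lists fixed before the data were examined (cell types, neighbouring tissues, pathways, RNA quality and sex-linked genes) could not be matched, and 0 were tested. The planned list tests, the shares of mitochondrial and haemoglobin counts, the sex-linked values and the test of neighbouring genes were not run for the same reason. The rule for named genes, fixed before the data were examined, took genes with an adjusted p under 0.05, an average log2 CPM (counts scaled to a common library size) of at least 1, a gene symbol and no overlap between the strains' libraries. It named the 10 with the largest fold change in each direction, the 5 most abundant in each direction, and members of the fixed lists. Without symbols it was reduced to the largest fold changes, with at most 2 IDs that rose and 2 that fell. Only 1 gene that rose met the rule, so 1 more that rose was chosen after its values were seen, as the largest rise without WKY replicate 4 among genes that met the same conditions in the other 7 libraries and had at least 10 counts in every library. Whether near-identical gene copies or antisense genes share reads with the named genes could not be checked.

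The total was 45048841 to 49560687 counts in the SHR libraries and 53045139 to 53699673 in the WKY libraries. Libraries of one strain were compared in pairs by a chi-square of their counts over genes with at least 40 counts in the pair. The chi-square per degree of freedom was at least 15.5, for SHR replicates 2 and 4, so no pair of libraries was treated as a duplicate.

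Differential expression was tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test on the deposited counts, with TMM scaling, the default filterByExpr filter and strain as the only term. Fold changes are SHR relative to WKY. The standard error of a log2 fold change was its size divided by the square root of F. P-values were two-sided and adjusted by Benjamini-Hochberg over the 16867 genes tested, and a gene was called at an adjusted p under 0.05. CPM values are TMM-scaled. On log2 scales, CPM carried a prior count of 2. Library measures were compared by exact permutation tests over 70 assignments, two-sided, with a smallest possible p of 0.0286.

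To place each library between the strains, edgeR was fitted without it and without WKY replicate 4, and the genes called were used. At each gene the library's log2 CPM was put on a scale from 0 at the mean of the WKY libraries in the fit to 1 at the mean of the SHR libraries in the fit. This check was chosen after the data were seen.

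The main test was fixed before the data were examined, as were these alternatives: RLE scaling, no filter on low counts, a stricter filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust empirical Bayes, the replicate number as a block, and each library left out in turn. Sample quality weights in limma, and repeats of the alternatives on the 7 libraries other than WKY replicate 4, were added after the data were seen.

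The edgeR test was tested on simulated data drawn from the means, dispersions and totals of these libraries. In it 200 genes with an average log2 CPM of at least 1 were changed. All simulated libraries of a strain shared the same mean at each gene, so none lay with the other strain. In the simulation of all 8 libraries over 16867 genes, 100% of 50 genes changed 4-fold were recovered, 74% of those changed 2-fold and 24% of those changed 1.5-fold, and 6 unchanged genes were called. In the simulation without WKY replicate 4 over 17029 genes, the shares recovered were 100% at 4-fold, 88% at 2-fold and 46% at 1.5-fold, and 9 unchanged genes were called.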

Results

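Gene expression in the hippocampus was compared between the spontaneously hypertensive rat (SHR), an inbred strain that develops high blood pressure, and the Wistar-Kyoto rat (WKY), the related strain used as its normotensive control. The comparison addressed which hippocampal transcripts differ in the hypertensive strain at 32 weeks of age. There were 4 libraries per strain. A count was present for 22544 of the 32623 annotated genes in at least 1 library, and 19075 to 19466 genes had a count in each library.

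Of 16867 genes tested, 6 differed between the strains over all 8 libraries, 1 higher and 5 lower in SHR, and all 6 by at least 2-fold. This count fell to 1 without WKY replicate 1, SHR replicate 1 or SHR replicate 4 and to 2 without WKY replicate 2, WKY replicate 3 or SHR replicate 2, and it rose to 458 without WKY replicate 4. The only gene that rose was ENSRNOG00000049070, which was at 6.18 ± 1.29 CPM in SHR and 1.01 ± 0.333 CPM in WKY (SD, n = 4 each). Its log2 fold change was 2.61 ± 0.27 (SE), a 6.09-fold rise (edgeR quasi-likelihood test, adjusted p = 0.0143). Among the called genes with an average log2 CPM of at least 1, the largest fall was in ENSRNOG00000018257, at 0.312 ± 0.107 CPM in SHR and 6.68 ± 2.19 CPM in WKY (SD, n = 4 each). Its log2 fold change was -4.41 ± 0.35 (SE), or 21.2-fold lower (edgeR, adjusted p = 0.00223). ENSRNOG00000022932 was at 3.15 ± 0.520 CPM in SHR and 9.33 ± 2.01 CPM in WKY, a log2 fold change of -1.56 ± 0.20 (edgeR, adjusted p = 0.0454). In each of these 3 genes the CPM of every SHR library lay outside the range of the WKY libraries, which the rule for naming them required. The files give no symbols for these IDs, and their functions are not described here.

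The fall of ENSRNOG00000018257 passed the test in all 15 alternatives, with log2 fold changes from -4.59 to -4.23. The rise of ENSRNOG00000049070 passed in 10 of 15, with log2 fold changes from 2.44 to 2.83 and adjusted p-values up to 0.124 in edgeR. It missed the threshold with the replicate number as a block (0.0747) and without WKY replicate 1 (0.124), SHR replicate 1 (0.0845), SHR replicate 2 (0.0602) or SHR replicate 4 (0.0760). The fall of ENSRNOG00000022932 passed in 5 of 15, with log2 fold changes from -1.68 to -1.42 and adjusted p-values up to 0.244 in edgeR. It missed the threshold with no low-count filter (0.0560), in limma-voom (0.0799), with the block (0.244) and without any one library (0.0862 to 0.219) other than WKY replicate 4. None of these 3 changed direction in any of the 15.

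Below the adjusted threshold, 2038 genes had an unadjusted p under 0.05 in the edgeR test, where 843 would be expected by chance, with 817 of them higher and 1221 lower in SHR. The CPM ranges of the strains did not overlap for 1135 genes, or 6.73% of those tested, where chance gives 2.86%. SHR was the higher strain in 470 of these and WKY in 665. With SHR replicate 3 in the place of WKY replicate 4, the ranges of the 4 and 4 libraries did not overlap for 1158 genes. With SHR replicates 1, 2 and 4 in its place the numbers of genes were 1054, 725 and 925. Each of these groupings kept WKY replicates 1 to 3 together, and WKY replicate 4 itself lay nearer to SHR at most called genes (below). They therefore cannot tell whether the excess over chance comes from strain. DESeq2 called 334 genes, including all 6 called by edgeR, and limma-voom called 5, of which 4 were among the 6. Another split of the same 8 libraries into 4 and 4 gave 359 genes with DESeq2, so its count was not larger than other groupings of these libraries can give.

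**Figure D1:**
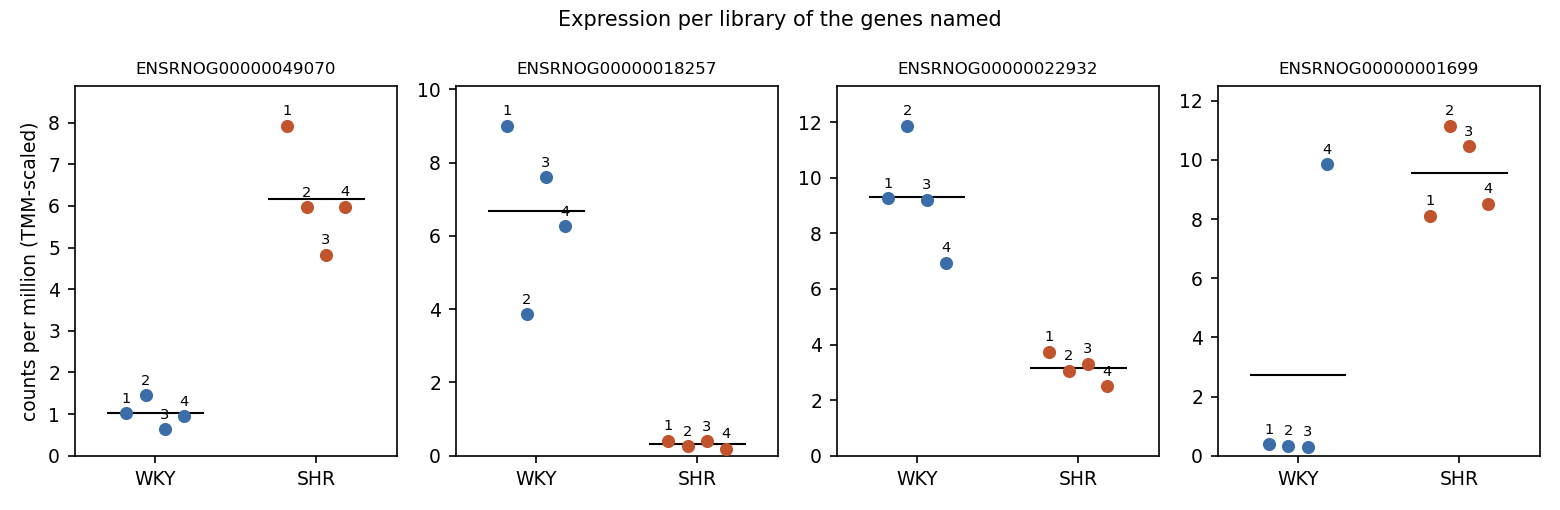
Expression of the 4 named genes in each library, as TMM-scaled CPM on linear axes that start at 0, with WKY in blue and SHR in orange. Points are single libraries labelled with their replicate number and lines are strain means (n = 4 each); in the right panel WKY replicate 4, at 9.86 CPM, lies among the SHR libraries.

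Without WKY replicate 4, 458 of 17029 genes differed between the strains, 197 higher and 261 lower in SHR (edgeR quasi-likelihood test, adjusted p under 0.05). Leaving out each library had been set before the data were examined, but this library was singled out because its removal gave the most genes of the 8. All 6 genes called over 8 libraries were among them, in the same direction. Of the 458, 179 differed by at least 2-fold, 83 higher and 96 lower in SHR. In 13 of the 458 every one of WKY replicates 1 to 3 had under 3 counts, and in 6 every SHR library had under 3 counts, so the fold changes of these genes depend on the prior count. The ranges of the strains did not overlap for 2943 genes without this library, or 17.3%, where chance gives 5.71%. Leaving out any other library in place of it gave 1 to 6 genes. With 1 more library left out beside it, the count was 315 without WKY replicate 1, 127 without WKY replicate 2, 217 without WKY replicate 3, 226 without SHR replicate 1, 199 without SHR replicate 2, 662 without SHR replicate 3 and 221 without SHR replicate 4.

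ENSRNOG00000001699, chosen after its values were seen, illustrates the difference. It was at 9.56 ± 1.48 CPM in SHR (SD, n = 4) and at 0.347 ± 0.048 CPM in WKY replicates 1 to 3 (SD, n = 3), while WKY replicate 4 was at 9.86 CPM, within the SHR range of 8.11 to 11.2 CPM. Over 8 libraries its log2 fold change was 1.81 ± 0.98 (SE; edgeR, adjusted p = 0.50). Without WKY replicate 4 the log2 fold change was 4.78 ± 0.22 (edgeR, adjusted p = 3.75e-06), a 27.4-fold rise in SHR. That was the only one of 14 alternatives in which it passed the test, and the adjusted p reached 0.779 in the others. DESeq2 over all 8 libraries, which is not among the 14, gave no p-value for this gene, whose Cook's distance in WKY replicate 4 (21.8) was above the outlier cutoff (10.9).

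**Figure D2:**
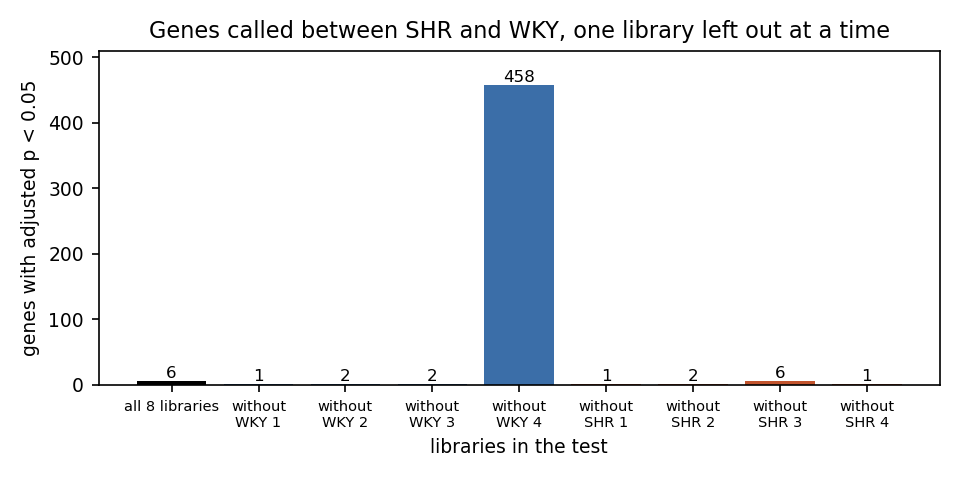
Number of genes with an adjusted p under 0.05 between SHR and WKY (edgeR, vertical axis) with all 8 libraries and with each library left out in turn (horizontal axis). The bar without WKY replicate 4 reaches 458 genes, against 6 with all libraries and 1 to 6 without any other library.

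Each library was then placed between the strains at genes called without it. WKY replicates 1, 2 and 3 had median positions of 0.216, 0.0202 and 0.133, near the WKY mean. SHR replicates 1, 2, 3 and 4 had medians of 0.937, 0.979, 0.816 and 0.936, near the SHR mean. WKY replicate 4 had a median of 0.882, with 372 of the 458 genes nearer to SHR and 86 nearer to WKY. At the 77 of these genes with a strain difference of at least 4-fold, WKY replicate 4 was nearer to SHR at 63 (81.8%). Each held-out SHR library was nearer to SHR at 92.6 to 100% of its own such genes. Of the 40 among the 77 that were higher in SHR, WKY replicate 4 was nearer to SHR at 38, and of the 37 that were lower in SHR at 25. The rule for the genes named from all 8 libraries required every WKY library to lie apart from SHR. Among them, WKY replicate 4 was at 0.950 CPM for ENSRNOG00000049070 and 6.26 CPM for ENSRNOG00000018257, within the range of the other WKY libraries. For ENSRNOG00000022932 it was at 6.95 CPM, below the other WKY libraries (9.22 to 11.9 CPM) and above the SHR libraries (2.50 to 3.75 CPM).

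**Figure D3:**
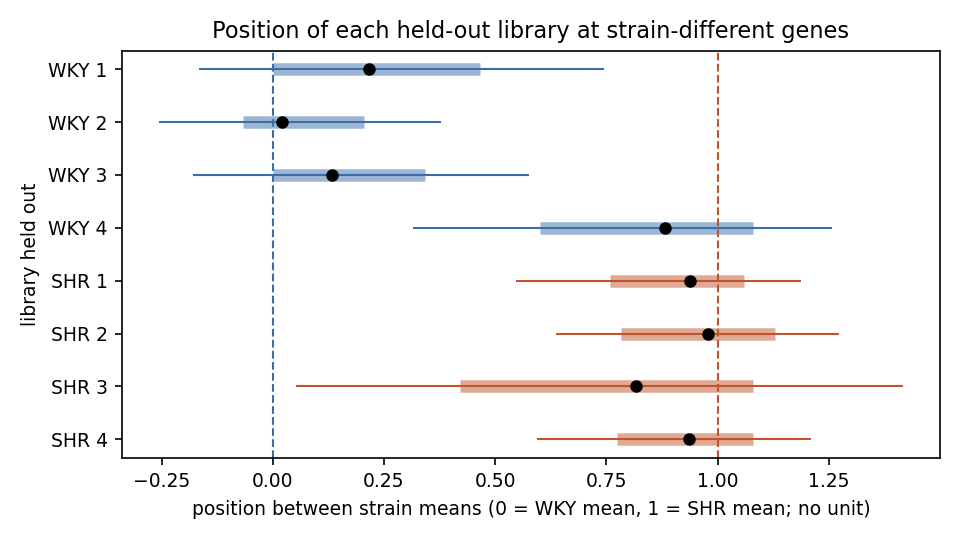
Position of each library (vertical axis) between the WKY mean at 0 and the SHR mean at 1 (horizontal axis, no unit), over the genes called without that library and without WKY replicate 4. Black points are medians over genes, thick bars the middle quartiles and thin lines the 10th to 90th percentiles; WKY replicate 4 has a median of 0.882, beside the SHR libraries at 0.816 to 0.979.

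On the first principal component of log2 CPM, which held 26.7% of the variance, WKY replicates 1, 2 and 3 scored -30.5, -39.6 and -40.9. The SHR libraries scored 11.6 to 28.9 and WKY replicate 4 scored 36.6. On the second component, with 19.98% of the variance, WKY replicate 4 scored 46.0, away from the SHR libraries (-38.1 to 11.5) and beyond the other WKY libraries (-3.52 to 17.6). Over all genes tested, the correlation of WKY replicate 4 averaged 0.965 with the other WKY libraries and 0.970 with the SHR libraries. Each of the other 7 libraries had its higher mean correlation with its own strain. WKY replicates 1, 2 and 3 averaged 0.972, 0.969 and 0.971 with the SHR libraries. Over all genes, WKY replicate 4 was therefore farther from the other WKY libraries, but its correlation with SHR was within their range. These correlations are across genes, which are not independent replicates. The biological coefficient of variation was 0.247 over the 4 WKY libraries, 0.194 over the 4 SHR libraries and 0.170 over WKY replicates 1 to 3.

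The SHR libraries had lower totals than the WKY libraries. The libraries held 47056356 ± 2095909 counts in SHR and 53338595 ± 301551 in WKY (SD, n = 4 each), with no overlap (exact permutation test, two-sided p = 0.0286, the smallest this design can give; Benjamini-Hochberg adjusted p = 0.143 over 5 library measures, the smallest that 1 such measure alone can reach). The number of genes with a count was 19226 ± 120 in SHR and 19329 ± 101 in WKY (exact permutation test, p = 0.257, adjusted p = 0.429). The 10 genes most abundant on average took 11.3 ± 1.9% of the counts in SHR and 11.9 ± 0.75% in WKY (exact permutation test, p = 0.600, adjusted p = 0.600).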

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

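Among the tests below, both tests of an SHR animal under a WKY label, that of mixed RNA, the positions and gap genes of WKY replicate 4, and the splits of all 8 libraries with edgeR were chosen after the result was seen. The other splits, the thinning and the test of absent genes were written down before their results were known. Of 24 sets of 4 libraries screened for a library far from the rest, 3 were picked out, where chance picks about 1 in 20. The sets are not independent, because they come from the same libraries and from related measures. The median held-out position of WKY replicate 4 (0.882) was screened too and was not picked out. The first principal component score of WKY replicate 4 (36.6) lay far from those of the other WKY libraries. So did its level of ENSRNOG00000001699 (9.86 CPM), a gene chosen because it showed this pattern. In SHR replicate 1 the 10 genes most abundant on average took 14.1% of the counts, above the other SHR libraries at 10.1 to 10.7%.

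WKY replicate 4 lay with the SHR libraries at most genes that separated them from WKY replicates 1 to 3. RNA of an SHR animal mixed into a WKY library that kept well above 0.1 of its own RNA is argued against. The test was written for a kept share of at least 0.1. At a true share near 0.1, however, spread between genes would also put many of them under 0.1, so such a share stays open. The WKY share at a gene was the library's linear CPM above the SHR mean, divided by the WKY mean minus the SHR mean. In WKY replicate 4 this share was under 0.1 at 23 of 37 genes at least 4-fold lower in SHR. Held-out WKY libraries were that low at no more than 1 gene. Held-out SHR replicates 1, 2, 3 and 4 were that low at 25 of 29, 23 of 28, 31 of 36 and 25 of 27 genes, larger shares than in WKY replicate 4. An SHR animal like the other 4 under a WKY label is also argued against. WKY replicate 4 was set apart from all 7 others, by a gap of at least 2 on the log2 scale, at 42 genes (36 higher in it). An SHR library was so at up to 7. At genes at least 4-fold lower in SHR it was nearer to WKY at 12 of 37, against up to 3 of 36 in a held-out SHR library. Over all called genes, however, WKY replicate 4 was nearer to SHR at 81.2%. That was more than held-out SHR replicate 3 (70.7%) and less than the other SHR libraries (93.4 to 96.0%). These shares rest on unlike gene lists, of 458 genes for WKY replicate 4, 662 for SHR replicate 3 and 199 to 226 for the others. At the genes with at least a 4-fold difference, WKY replicate 4 was nearer to SHR at 81.8%. There it was below SHR replicate 3 (92.6%) and the other SHR libraries (95 to 100%). An SHR animal under a WKY label, with RNA of a further source, stays open. At the 40 genes at least 4-fold higher in SHR, WKY replicate 4 was nearer to WKY at 2 (5%), against up to 9.09% in a held-out SHR library. This met the outcome written for that explanation. The test could not count in its favour, because that also required no more genes with a gap than an SHR library, already known to fail (42 against 7). A genotype unlike that of WKY replicates 1 to 3 also stays open, as an untested biological difference does: it lacked 1 gene that all 7 others held at 30 or more counts, and other libraries lacked up to 2.

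Some of these tests replaced earlier ones after results were seen. Mixing was tested first on 2 genes present in WKY replicates 1 to 3 and absent in SHR. In WKY replicate 4, 1 had under 3 counts and 1 had 30 or more. All 3 genes present in SHR and absent in WKY replicates 1 to 3 had 30 or more counts in it. Mixing was tested next on low linear shares of the SHR level, and then on WKY shares, as described above, over 0.5 (6 of 37 genes, against up to 3 in an SHR library). None of these 3 tests decided, and the WKY share under 0.1 was the next one tried. The SHR label was tested first on the genes with a gap, and that result (42 against 7) counted against an animal like the other SHR libraries. The test on genes higher in SHR was added after that, for an SHR animal with RNA of a further source, which could not be tested with tissue markers. For the genotype, the outcome set beforehand as counting against it (no more absent genes than the highest other library) was met, at 1 against 2. It is read as undecided because every library lacked only 0 to 2 such genes. The minimum of 5 genes for a decision was set after that result was seen. An exchange of labels within the series was also tested, and no SHR library lay with WKY (lowest median position 0.816).

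Over all 8 libraries the split by strain stood out for edgeR and did not for DESeq2. With edgeR, the real split of the 8 libraries called 6 genes and the highest of the other splits 2. Thus 1 of 35 splits reached 6, the smallest share this check can give. The check was chosen after the result was seen, so it does not exclude chance. Without WKY replicate 4 the real split called 458 genes and the highest other 1, again 1 of 35 splits. The library left out was chosen among 8 for its effect on the real split and on no other, and the splits are too few to allow for that choice. With DESeq2, 2 of 35 splits gave at least the real 334 genes, so chance cannot be excluded. The other of these splits, which exchanged WKY replicate 3 for SHR replicate 3, gave 359. Putting SHR replicates 1 to 4 in turn in the place of WKY replicate 4 gave 0 genes each with edgeR and 142 to 310 with DESeq2.

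The lower depth of the SHR libraries is argued against as the source of the 458 genes called without WKY replicate 4. After every library was thinned to the smallest total, 445 of the 458 were still called. Thinning treated the counts as single fragments, which low counts here were not taken to be. It tested depth only. The totals of the strains did not overlap, so a step of preparation or sequencing that differed in the same way cannot be told apart from strain.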

How the results depend on the processing

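Sample quality weights and all alternatives without WKY replicate 4 other than leaving it out were chosen after the data were seen. Over all 8 libraries, the main results were 6 genes called, all at least 2-fold, and 16.7% of them higher in SHR. With no low-count filter 3 were called, all at least 2-fold. DESeq2 called 334 (84 at least 2-fold). Sample quality weights gave 234 (90 at least 2-fold, 52.6% higher in SHR) with the lowest weights for WKY replicate 4 (0.467) and SHR replicate 3 (0.526). RLE scaling, limma-voom, the stricter filter and robust empirical Bayes gave 4 to 6 genes. Leaving out each library in turn gave 1 to 458 genes, 1 to 179 at least 2-fold and 0 to 66.7% higher in SHR. The highest counts were without WKY replicate 4, and counts fell to 1 without WKY replicate 1, SHR replicate 1 or SHR replicate 4 and to 2 without WKY replicate 2, WKY replicate 3 or SHR replicate 2. Without SHR replicate 3 there were 6, of which 3 were at least 2-fold. The replicate block gave 1 gene, at least 2-fold and lower in SHR (0% higher). The deviations of same-numbered libraries from their strain means correlated at -0.157 to -0.00340, no library correlated best with its own number, and 4 titles carry another number than the file headers, so the numbers were not taken to pair the libraries. Without WKY replicate 4, the 458 genes (179 at least 2-fold, 43.0% higher in SHR) became 302 with no filter and 1216 with DESeq2 (279 at least 2-fold, 49.7% higher in SHR), which included all 458. The other 4 settings gave 436 to 477. Leaving out 1 more library gave 127 (WKY replicate 2) to 662 (SHR replicate 3) genes, 95 to 186 at least 2-fold and 39.7 to 52.9% higher in SHR. The counts were also over 1.5 times lower without WKY replicate 3 (217), SHR replicate 1 (226), SHR replicate 2 (199) and SHR replicate 4 (221). Fits of the same number of libraries gave 315 without WKY replicate 1 and 662 without SHR replicate 3, so the count depended on which library was left out. The cause was not tested for these or other changes. The gene list tests with their alternatives, the mitochondrial and haemoglobin shares, and the single-library tables as input were not run, the last because they hold the same values as the matrix. In simulations of the 8 libraries 24% of genes changed 1.5-fold were recovered, so changes of that size mostly escaped the test there. No simulated library lay with the other strain as WKY replicate 4 did, so these shares need not hold for the real libraries.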
